A study of Homo sapiens with 6 samples.

How the data were processed

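Polyadenylated RNA was sequenced from U2OS cells, an established human osteosarcoma line, 48 hours after lipid transfection with a scrambled control siRNA or with siRNA against ALKBH5, per the labels' protocols. The libraries were made with a stranded mRNA kit and read as single reads of 50 bases. There were 6 libraries, 3 per group, and each was placed in its group by its label. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

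The deposited values are raw read counts per gene symbol, with no normalisation, per the file headers. The submitters' processing notes name CASAVA 1.8.2, TopHat2, SAMtools and HTSeq and the genome build hg19. Their settings, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene can therefore not be separated, and counts of near-identical gene copies are uncertain because reads with more than 1 placement were left out of the counts. Each file lists 23228 gene symbols and HTSeq's own summary entries. A table of the whole series held the same values as the files of the single samples in all 23233 lines, and 0 of its columns matched no sample. The summary entries were kept out of library sizes and tests. Reads placed uniquely but outside genes made up 15.3% ± 0.23 of uniquely placed reads in the scrambled libraries and 17.9% ± 0.66 in the ALKBH5 knockdown libraries (SD, n = 3), and ambiguous reads made up 0.836% ± 0.021 and 0.746% ± 0.0081. Entries with more than 1 placement took 33.3% ± 0.33 and 33.0% ± 0.18 of all entries.

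Reads in genes numbered between 18817181 and 23410007 per library, so a gene at 1 CPM rests on about 18.8 to 23.4 reads per library. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom between 6.21 and 17.2), so none was taken for a repeat of another.

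Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 14504 genes, libraries were scaled with TMM, and groups were compared with a robust quasi-likelihood fit (glmQLFit, glmQLFTest, 2-sided) with group as its single term. P-values were adjusted with the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes are ALKBH5 siRNA over scrambled siRNA. CPM values are scaled with TMM factors and given as mean ± SD over 3 libraries. For ALKBH5 an exact 2-sided permutation test of CPM was also run. With 3 libraries against 3 its smallest p is 0.1.

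Gene lists, 29 in number, were fixed before the data were examined. They covered m6A writers, m6A readers, FTO and the ALKBH family, histone ubiquitination, DNA replication, mitosis, G1/S regulators, DNA repair, p53 targets, apoptosis, interferon response, NF-kB and inflammation, the integrated stress and unfolded protein responses, cholesterol synthesis, hypoxia and glycolysis, extracellular matrix, osteoblast genes, YAP/TEAD targets, TGF-beta/BMP, Wnt, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, immediate early genes, replication histones, the siRNA pathway, and markers of epithelial cells, leukocytes and endothelial cells. Lists with at least 5 tested members were compared with all other tested genes by limma 3.58.1's camera on log2 CPM (prior count 2, preset correlation 0.01). Camera with an estimated correlation and fry were run beside it. Adjusted p-values of lists are over the 29 lists.

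The named genes were chosen by a rule set before the data were examined. It took ALKBH5, the 8 higher and 8 lower genes with the largest log2 fold change among changed genes with an average log2 CPM of at least 2 and groups that did not overlap, the up to 3 changed members of each list with the smallest adjusted p, and METTL3, METTL14, FTO, YTHDF2, USP22 and RNF40. USP22 and RNF40 were included from prior knowledge of work on ALKBH5, not from the labels. Some genes that the rule takes are not reported here.

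The gene test was tested on simulated counts drawn for this comparison with 200 genes changed. Of the 14382 simulated genes that were tested, it recovered 62.7% of those changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold, with 6 false calls among 175. In the data 61.6% of tested genes were called, far more than were changed in the simulation. The simulation therefore cannot check the scaling or the error rate for a change that wide.

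Alternatives were RLE scaling, library totals with no scaling factor, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit without robust moderation, glmTreat against a 1.5-fold change, the replicate number as a block, and each library left out in turn. A correction for GC content and transcript length was added after seeing the data. It used GENCODE 29 transcripts, which gave values for 13337 of the 14504 tested genes (92.0%). Gene symbols were matched to GENCODE 29 by name (17366 symbols) or through a current or older symbol (1384), and 4478 had no single match. Sequences of 3′ UTRs came from 1 protein-coding transcript per gene, and 13030 tested genes had a 3′ UTR of at least 50 bases. The log2 fold change was regressed on the presence of each of 4096 hexamers, with the logarithm of the UTR length, the base composition and the average abundance as covariates. The hexamer scan found a planted hexamer in simulated data. Coordinates are not given, because the files hold gene symbols without positions.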

Results

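Gene expression was measured by RNA-seq in U2OS cells, a human osteosarcoma line, transfected for 48 hours with scrambled siRNA (3 libraries) or with siRNA against ALKBH5 (3 libraries). ALKBH5 removes the methyl group of N6-methyladenosine (m6A) in RNA. The comparison asks which transcripts differ between cells given siRNA against ALKBH5 and cells given scrambled siRNA. These data hold no knockdown with another siRNA and no rescue. Effects of ALKBH5 loss and other effects of either siRNA can therefore not be told apart. Reads in genes numbered 18817181 to 23410007 in the scrambled libraries and 19748583 to 19919797 in the knockdown libraries. Reads placed uniquely outside genes were 15.3% ± 0.23 of uniquely placed reads in the scrambled and 17.9% ± 0.66 in the knockdown libraries (SD, n = 3). The 1st principal component of log2 CPM held 83.3% of the variance and separated the groups.

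ALKBH5 itself fell in every knockdown library. Its level was 143 ± 4.92 CPM in the scrambled libraries and 17.1 ± 2.06 CPM in the knockdown libraries (SD, n = 3), an 8.35-fold lower level. The log2 fold change was −3.06 (SE 0.10, adjusted p = 1.6e-09). The single knockdown libraries held 19.4, 16.2 and 15.7 CPM, or 380, 307 and 306 reads, against 138, 148 and 143 CPM in the controls. An exact permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 libraries allow.

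**Figure D1:**
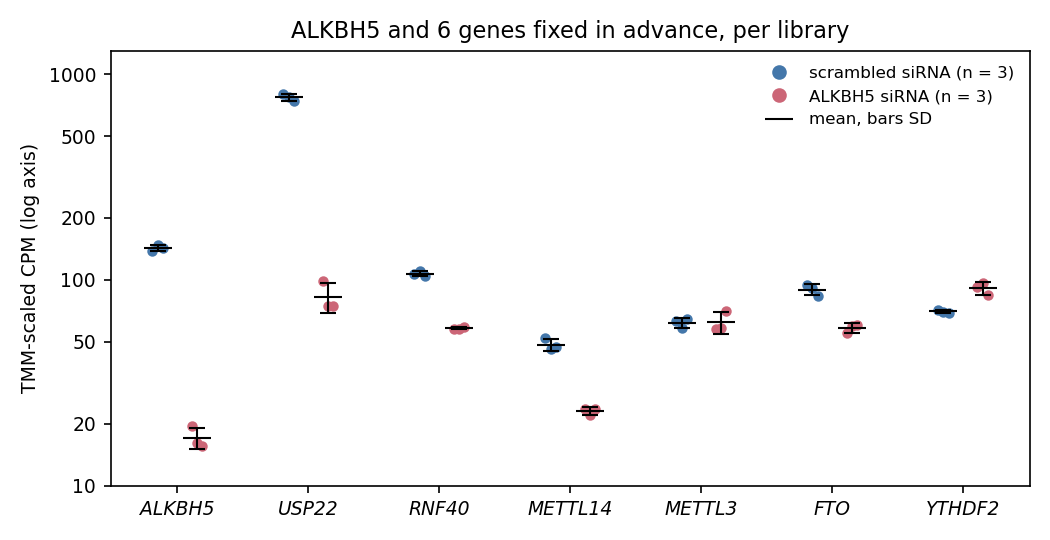
TMM-scaled CPM (log axis) of ALKBH5 and of the 6 genes fixed by name, with each library as a point and the mean and SD of the 3 libraries per group in black. ALKBH5 dropped from 143 to 17.1 CPM and USP22 from 772 to 82.5 CPM, while METTL3 stood at 62.0 CPM in the scrambled libraries and 62.3 CPM in the knockdown.

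Expression differed widely between the groups. Of 14504 tested genes, 4471 were higher and 4466 lower, together 61.6%. The median absolute log2 fold change of the 8937 changed genes was 0.73, with quartiles of 0.45 and 1.16. By size, 1542 genes were higher and 1354 lower by 2-fold or more, and 330 and 301 by 4-fold or more. The CPM values of the groups did not overlap in 67.4% of tested genes, against 10% that chance gives for 3 libraries against 3. When tested against a change of 1.5-fold with glmTreat, 1891 genes were higher and 1710 lower.

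The 8 largest increases named by the rule spanned log2 fold changes of 3.89 to 6.95. ACTG2, the smooth muscle gamma actin, rose from 0.576 ± 0.18 to 72.2 ± 17.4 CPM (log2 fold change 6.95, SE 0.26, adjusted p = 1.6e-08). PDGFB, a platelet-derived growth factor chain, rose from 2.72 ± 0.61 to 77.0 ± 1.43 CPM (log2 fold change 4.81). TAGLN, the actin-binding protein transgelin, reached 874 ± 137 CPM from 58.2 ± 4.50 CPM (log2 fold change 3.91). EPPK1, which encodes the cytoskeletal linker epiplakin, rose by 4.83 on the log2 scale, and the protocadherin gene PCDH1 by 4.12. FLJ46300, LOC100506394 and C5orf46 rose by 4.23, 3.98 and 3.89 on that scale. Reads of ACTG2 are uncertain where its sequence is shared with other actins.

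The largest decreases were in genes of moderate or low abundance. KRT14, a keratin of basal epithelial cells, fell from 8.34 ± 1.88 to 0.362 ± 0.29 CPM (log2 fold change −4.51, SE 0.41, adjusted p = 4.6e-06). METTL7A, a methyltransferase-like protein, had a log2 fold change of −4.00, and MANSC4 of −3.56. GAMT, which makes creatine from guanidinoacetate, fell from 35.8 ± 3.07 to 3.28 ± 0.57 CPM. C15orf38 (log2 fold change −3.71), CYYR1 (−3.51), UNC80 (−3.50), a subunit of a sodium leak channel complex, and VASH2 (−3.32), a vasohibin, completed the set. Counts of KRT14 are uncertain because keratins and their pseudogenes share sequence, and C15orf38 is joined to its neighbour AP3S2 by read-through transcripts.

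**Figure D2:**
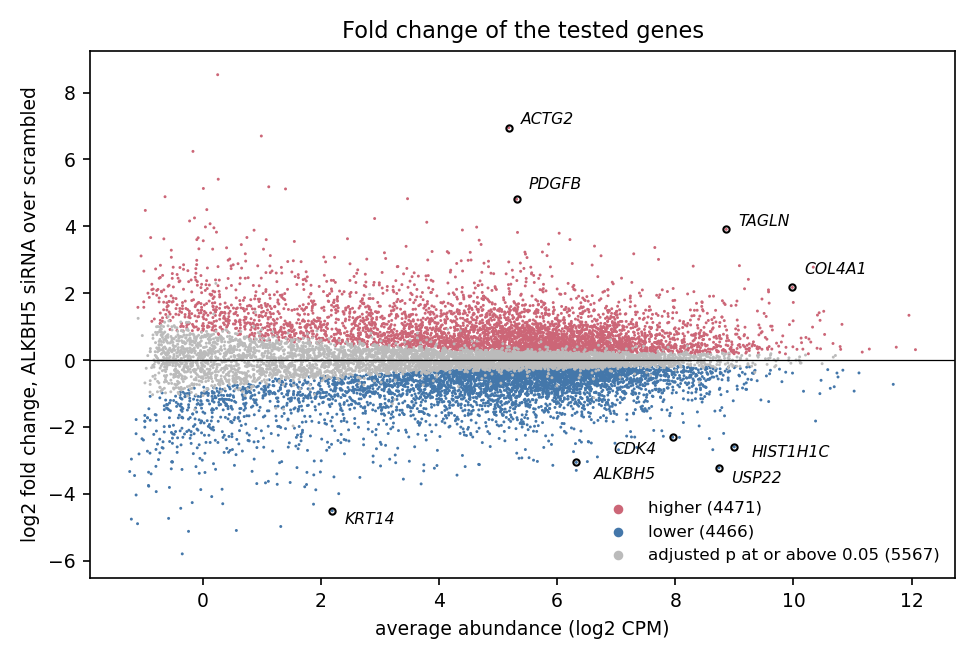
Log2 fold change (ALKBH5 siRNA over scrambled siRNA) against average abundance (log2 CPM), with each point 1 of the 14504 tested genes, coloured by direction where the adjusted p was under 0.05. The 4471 higher and 4466 lower genes span most of the range of abundance, and circles mark genes named in the text, such as ACTG2 at 6.95 and ALKBH5 at −3.06.

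Some m6A writer genes fell, and the others did not differ detectably. Of 10 writer genes, 5 were lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.69 with an estimated correlation). ZC3H13 and RBM15B, adaptors of the writer complex, fell by 1.27 and 1.04 on the log2 scale, and METTL14 fell from 48.4 ± 3.22 to 23.0 ± 0.97 CPM (log2 fold change −1.07). METTL3, the catalytic subunit, did not differ detectably (62.0 ± 3.36 against 62.3 ± 7.47 CPM, log2 fold change 0.01, SE 0.10, adjusted p = 0.95). The list's call was lost without scrambled replicate 3 (adjusted p = 0.067) and without knockdown replicate 1 (adjusted p = 0.115).

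The m6A readers went both ways. Of 12 readers, 4 were higher and 5 lower, and 4 and 6 adjusted over the list alone (camera adjusted p = 0.63). YTHDF3 rose from 80.4 ± 2.45 to 139 ± 8.67 CPM and YTHDF2, which promotes decay of methylated RNA, from 70.3 ± 1.04 to 91.1 ± 6.29 CPM (log2 fold change 0.37, adjusted p = 0.0018). FMR1 fell by 1.85 and RBMX by 1.07 on the log2 scale. Among FTO and the other ALKBH genes, 2 of 8 were higher and 2 lower, with the same numbers adjusted over the list alone (camera adjusted p = 0.80). FTO, the other m6A demethylase, fell from 89.8 ± 5.64 to 58.4 ± 3.08 CPM (log2 fold change −0.62), and ALKBH8 rose by 0.76. The 3′ UTR of FTO (10026 bases) held 8 copies of the hexamer GAGATG, taken up under Other observations. At least as many were in 6.86% of genes with a 3′ UTR of similar length. ALKBH1 rose by 0.37, and its call was lost without scrambled replicate 1 (adjusted p = 0.064) and without scrambled replicate 2 (adjusted p = 0.056).

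USP22, which removes ubiquitin from histone H2B, fell about as far as ALKBH5. Its level went from 772 ± 31.8 to 82.5 ± 13.8 CPM (9.35-fold lower, log2 fold change −3.22, SE 0.11, adjusted p = 2.5e-09). RNF40, part of the ligase that adds ubiquitin to H2B, fell from 107 ± 2.81 to 58.4 ± 0.74 CPM (log2 fold change −0.88, SE 0.08, adjusted p = 1.2e-06). The 3′ UTR of USP22 (3438 bases in the GENCODE 29 transcript used) held 8 copies of the hexamer GAGATG, and that of RNF40 (2193 bases) held 1. In the list of histone ubiquitination genes, 7 of 33 were higher and 13 lower, with these numbers also adjusted over the list alone (camera adjusted p = 0.27). PCGF5, a Polycomb subunit, rose by 1.69, and the ubiquitin ligase gene DZIP3 fell by 1.11 on the log2 scale.

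Genes of cell division fell together. In the mitosis list 34 of 42 genes were lower and 1 higher, or 35 and 1 adjusted over the list alone (camera adjusted p = 2.8e-07; adjusted p = 0.69 with an estimated correlation). Cyclin B1 (CCNB1) fell from 495 ± 16.6 to 169 ± 8.32 CPM, the spindle checkpoint gene MAD2L1 from 98.3 ± 6.32 to 29.3 ± 3.81 CPM, and PRC1, which bundles midzone microtubules, from 312 ± 6.61 to 132 ± 8.91 CPM. In the DNA replication list 31 of 40 genes were lower and 2 higher, with the same numbers adjusted over the list alone (camera adjusted p = 4.7e-06; adjusted p = 0.69 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell 4.97-fold, TIMELESS, which protects replication forks, 3.15-fold, and the helicase subunit MCM7 2.84-fold. Among replication histones 13 of 15 were lower and 1 higher by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.00039; adjusted p = 0.69 with an estimated correlation). HIST1H1C, a linker histone, fell from 878 ± 66.8 to 145 ± 18.9 CPM, HIST1H2BK from 465 ± 19.5 to 226 ± 8.02 CPM and HIST1H4H from 14.4 ± 1.04 to 3.44 ± 1.00 CPM. Histone counts are uncertain because copies share sequence, and most replication histone messages lack a poly(A) tail.

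Regulators of the G1/S step were mixed as a list, with 8 of 28 higher and 11 lower, or 9 and 11 adjusted over the list alone (camera adjusted p = 0.36). CDK4, the kinase of D-type cyclins, fell from 413 ± 26.0 to 83.4 ± 3.42 CPM (log2 fold change −2.31, SE 0.08, adjusted p = 2.1e-09). CDK2 and its partner cyclin E1 (CCNE1) fell by 1.34 and 1.59 on the log2 scale. DNA repair genes were lower in 25 of 51 cases and higher in 10, with the same numbers adjusted over the list alone (camera adjusted p = 0.15). The mismatch repair gene PMS2 fell by 1.47 and TP53BP1 by 0.97 on the log2 scale. Of 37 p53 targets 18 were higher and 11 lower, or 19 and 11 adjusted over the list alone (camera adjusted p = 0.45). RRM2B, the p53-induced ribonucleotide reductase subunit, rose from 125 ± 3.16 to 376 ± 49.7 CPM, EDA2R rose 2.41-fold and SESN2 1.99-fold. Among apoptosis genes 14 of 28 were higher and 6 lower, with the same numbers adjusted over the list alone (camera adjusted p = 0.15). Cytochrome c (CYCS) rose by 1.83 and the anti-apoptotic gene MCL1 by 0.92 on the log2 scale.

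**Figure D3:**
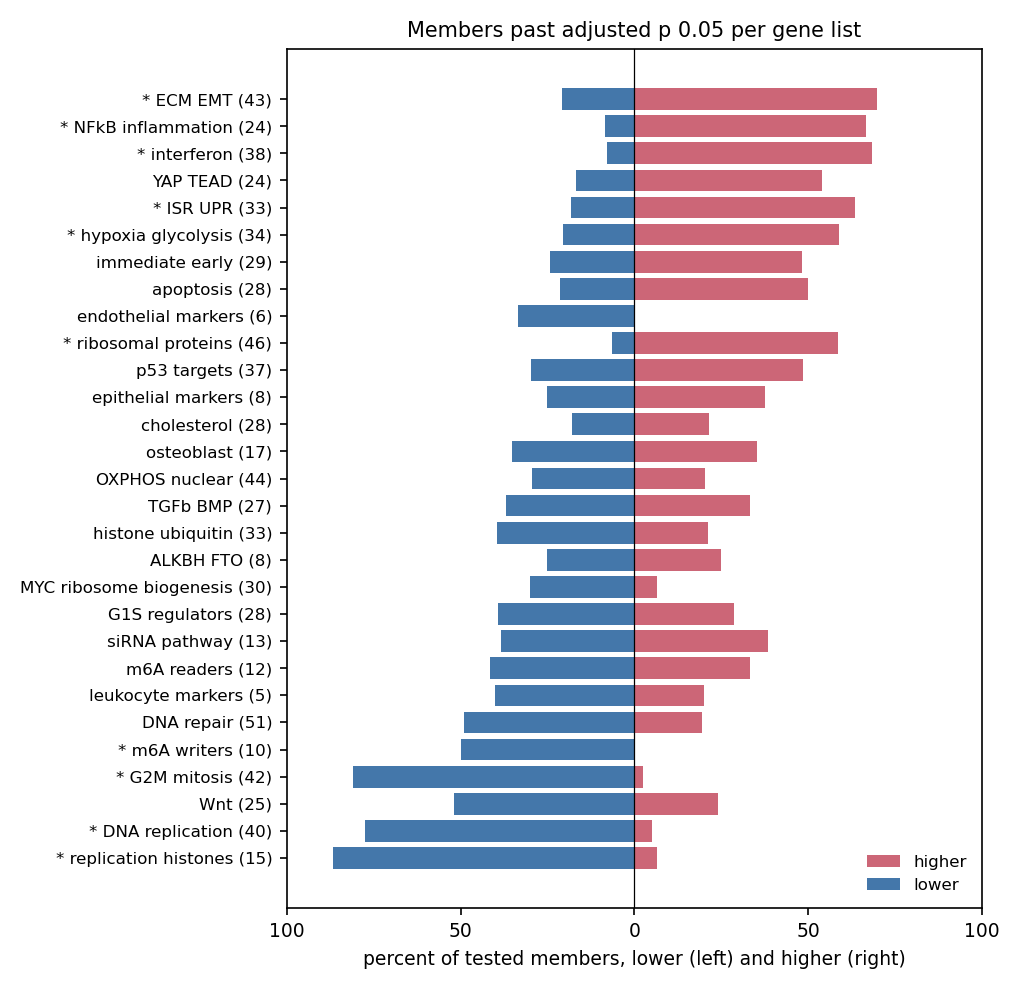
Share of tested members of each of the 29 gene lists that were lower (left, percent) or higher (right, percent) at an adjusted p under 0.05, with the number of tested members in brackets, ordered by median log2 fold change. Stars mark the 10 lists past the camera threshold, of which 6 were shifted up and 4 down; 0 lists passed with an estimated correlation.

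Interferon response genes rose. Of 38 tested, 26 were higher and 3 lower, with the same numbers adjusted over the list alone (camera adjusted p = 2.9e-05; adjusted p = 0.69 with an estimated correlation). IFIH1, a sensor of double-stranded RNA, rose from 3.11 ± 0.066 to 16.2 ± 0.59 CPM, the immunoproteasome subunit PSMB9 from 3.37 ± 1.05 to 32.0 ± 2.02 CPM and IFITM2 from 18.4 ± 0.57 to 55.9 ± 5.14 CPM. In the NF-kB and inflammation list 16 of 24 genes were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.69 with an estimated correlation). TNFAIP2 rose 2.49-fold, the mitochondrial superoxide dismutase SOD2 2.11-fold and CYLD, a deubiquitinase that restrains NF-kB signalling, 1.96-fold.

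The list of the integrated stress and unfolded protein responses had 21 of 33 genes higher and 6 lower, or 22 and 6 adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.69 with an estimated correlation). TRIB3, an ATF4 target, rose from 50.2 ± 4.62 to 136 ± 15.3 CPM, and both chains of an amino acid transporter, SLC7A5 and SLC3A2, rose 2.25-fold and 2.01-fold. Outside the naming rule, the 6 lower genes included ASNS (554 ± 47.7 to 309 ± 21.8 CPM) and HSP90B1 (718 ± 24.2 to 482 ± 26.0 CPM). HSPA5 did not differ detectably (adjusted p = 0.39), so the list did not move as 1 response. Of the hypoxia and glycolysis genes 20 of 34 were higher and 7 lower, or 22 and 7 adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.92 with an estimated correlation). The glucose transporter SLC2A1 rose from 164 ± 11.3 to 539 ± 30.2 CPM and the mitophagy receptor BNIP3L from 186 ± 13.7 to 426 ± 40.4 CPM, while the glycolytic enzyme TPI1 fell 2.29-fold. Without knockdown replicate 3 this list's call was lost (adjusted p = 0.052). Cholesterol genes were mixed, with 6 of 28 higher and 5 lower by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.80). SCD, a fatty acid desaturase, fell from 355 ± 54.0 to 81.8 ± 14.5 CPM, whereas SQLE and the sterol-responsive factor SREBF2 rose 2.81-fold and 1.85-fold.

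Matrix and adhesion genes rose. In the extracellular matrix list 30 of 43 genes were higher and 9 lower, or 30 and 10 adjusted over the list alone (camera adjusted p = 0.00030; adjusted p = 0.69 with an estimated correlation). The integrin subunit ITGAV rose from 191 ± 8.45 to 1016 ± 121 CPM (log2 fold change 2.41, SE 0.09), the basement membrane collagen COL4A1 from 368 ± 22.5 to 1656 ± 178 CPM and the fibrillar collagen COL5A1 by 2.04 on the log2 scale. The hexamer GAATAT, taken up under Other observations, was in the 3′ UTR of 16 of the 30 higher genes. It was in 44.2% of the list's 43 genes and in 34.1% of all 3′ UTRs scanned. ITGAV held 4 copies, COL4A1 1 and COL5A1 0. Targets of YAP and TEAD were higher in 13 of 24 cases and lower in 4, with the same numbers adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.053). This list passed without scrambled replicate 2 (adjusted p = 0.039) and without knockdown replicate 3 (adjusted p = 0.016). CYR61, a matricellular protein, rose 3.75-fold, CRIM1 4.13-fold and DLC1 2.53-fold. Outside the naming rule, the 4 lower genes included CTGF (433 ± 12.9 to 341 ± 43.2 CPM) and YAP1 itself (116 ± 3.13 to 73.7 ± 9.29 CPM).

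Signalling lists of bone and development went both ways. TGF-beta and BMP genes were higher in 9 and lower in 10 of 27 cases by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.80), with the receptors TGFBR2 and ACVR1 up by 0.98 and 1.15 and LTBP1, which stores TGF-beta in the matrix, at −1.33. Wnt genes were lower in 13 and higher in 6 of 25 cases, or 13 and 7 adjusted over the list alone (camera adjusted p = 0.22). Beta-catenin (CTNNB1) fell from 419 ± 14.2 to 138 ± 7.85 CPM and the Wnt modulator DKK3 1.83-fold, while GSK3B rose 1.66-fold. Osteoblast genes, the markers of the line's own origin, were higher in 6 and lower in 6 of 17 cases, also adjusted over the list alone (camera adjusted p = 0.97). Their median log2 fold change was 0.01 and their mean −0.05, and camera's direction was down. SMAD5 rose by 1.31 on the log2 scale, while BMP4 fell from 193 ± 17.8 to 53.8 ± 16.6 CPM and SMAD6 from 39.4 ± 3.99 to 15.3 ± 4.65 CPM.

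Ribosomal protein genes moved up slightly, with 27 of 46 higher and 3 lower by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.0077; adjusted p = 0.92 with an estimated correlation). Their median log2 fold change was 0.23. RPL22 rose 1.67-fold and RPS19 1.43-fold, and counts of this family are uncertain because its many pseudogenes share sequence. Ribosome biogenesis genes were lower in 9 and higher in 2 of 30 cases, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.27), with NPM1, WDR12 and FBL at log2 fold changes of −0.83, −0.88 and −0.76. Nuclear genes of oxidative phosphorylation were higher in 9 and lower in 13 of 44 cases, or 8 and 12 adjusted over the list alone (camera adjusted p = 0.61). The median of that list was 0.01, its mean −0.10 and camera's direction down. NDUFB5 of complex I fell 2.45-fold, and UQCRC2 and UQCRB of complex III fell 2.16-fold and 2.41-fold.

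Of the immediate early genes 14 of 29 were higher and 7 lower, or 14 and 8 adjusted over the list alone (camera adjusted p = 0.26). The phosphatase gene DUSP5 rose from 27.2 ± 2.12 to 107 ± 11.7 CPM and KLF2 from 4.03 ± 0.44 to 18.2 ± 2.10 CPM. Genes of the siRNA pathway were higher in 5 and lower in 5 of 13 cases, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.80). The Argonaute gene EIF2C1 fell and EIF2C3 rose, by log2 fold changes of −0.70 and 0.71, and TNRC6B, which binds Argonaute, had a log2 fold change of −0.68.

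**Figure D4:**
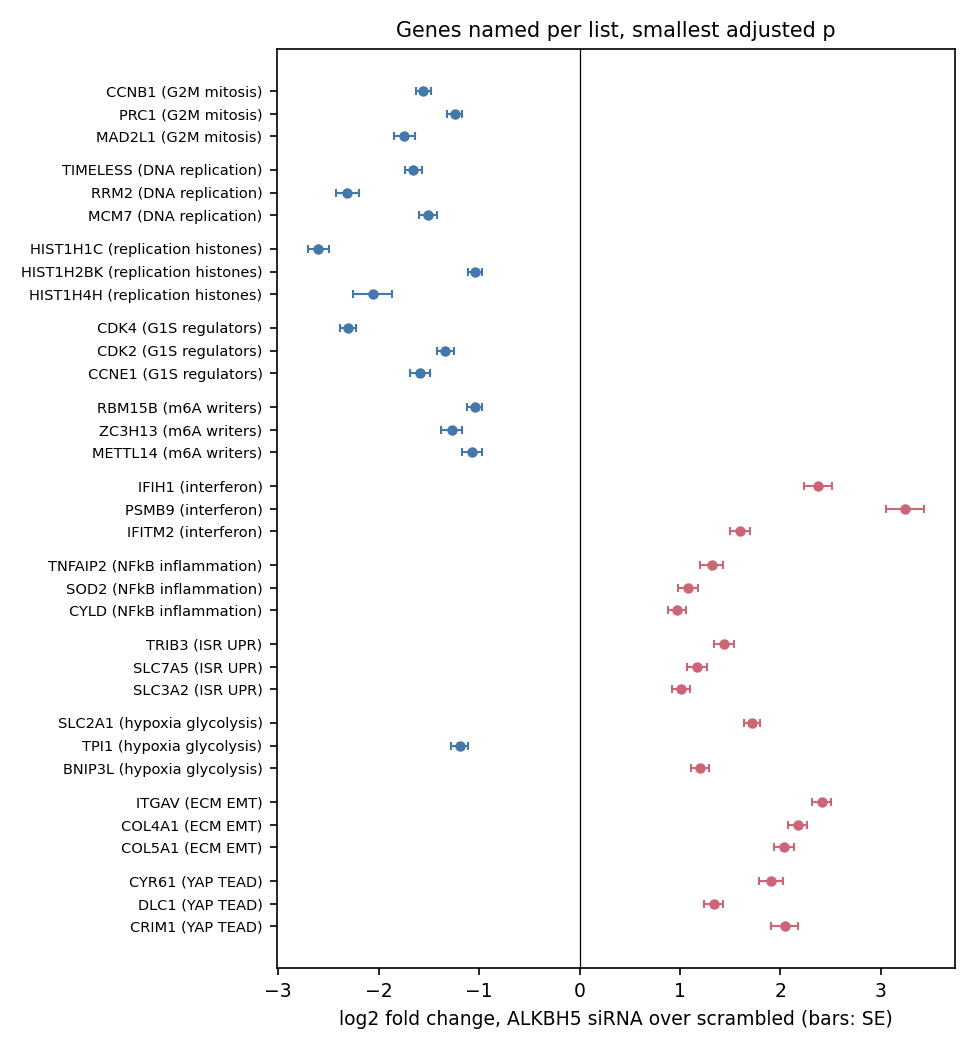
Log2 fold change (ALKBH5 siRNA over scrambled siRNA) of the up to 3 named genes of 11 lists, with SE as bars. The mitosis, replication, histone, G1/S and m6A writer genes lie left of 0, and all others except TPI1 lie right of 0, up to PSMB9 at 3.24.

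No list of markers of other cell types passed camera. Of the epithelial markers 3 of 8 tested were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.80). CLDN4, a tight junction claudin, rose from 34.2 ± 2.36 to 71.8 ± 5.65 CPM, KRT14 fell as above, and CLDN7 stood at 1.53 ± 0.37 CPM in the scrambled and 0.275 ± 0.056 CPM in the knockdown libraries. Of the leukocyte markers 1 of 5 was higher and 2 lower by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.80). LCP1, an actin-bundling protein, rose from 18.2 ± 1.90 to 135 ± 51.5 CPM. The calls of PTPRC and CORO1A were lost when single libraries were left out, with adjusted p-values up to 0.099 for PTPRC and 0.171 for CORO1A. Of the endothelial markers 0 of 6 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.80; fry adjusted p = 0.029), with VWF at 5.62 ± 0.99 and 0.857 ± 0.47 CPM and KDR at 1.05 ± 0.0082 and 0.0692 ± 0.060 CPM. Median and mean differed in sign for the epithelial (0.07 and −0.47, camera up), leukocyte (−0.20 and 0.20, camera down) and endothelial markers (0.27 and −0.82, camera down).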

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

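The tests in this part were set down before their results were seen; the difference they address had been seen. Reads placed uniquely but outside genes were not used in any comparison, and their share was higher in the knockdown libraries than in the controls. The share was 17.9% ± 0.66 against 15.3% ± 0.23 (SD, n = 3), each knockdown library lay above each control, and the exact permutation p was 0.1, the smallest this design allows.

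Genomic DNA in the knockdown libraries could raise this share, and would also raise reads in silent genes. Reads in 376 olfactory receptor genes stood at 10.7 ± 0.48 CPM of uniquely placed reads in the knockdown and 10.4 ± 0.096 in the controls, a ratio of 1.03 with overlapping groups, against 1.17 for reads outside genes. More unspliced RNA could do the same, but reads in 364 SNORD and SNORA genes, most of which lie in introns, had a ratio of 1.098 with overlapping groups (91.0 ± 15.2 against 82.9 ± 15.7 CPM of uniquely placed reads). Both explanations predicted that each knockdown library would lie above each control, and neither class of genes showed that. Neither ratio was under 1.0, the bound set for excluding an explanation. An absent cause would give a ratio near 1.0, so this bound can fail to exclude it. Both explanations therefore stay open and cannot be told apart with counts that hold no positions. An effect of ALKBH5 loss on transcripts outside the annotation stays open too, as untested.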

How the results depend on the processing

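ALKBH5 kept its direction and its call under every alternative run, with log2 fold changes between −3.16 and −2.96. Under the alternatives other than glmTreat the numbers of higher and lower genes stayed within 1.5 times those reported. They ranged from 3899 to 4391 higher and 3979 to 4325 lower with single libraries left out. Against a 1.5-fold change glmTreat called 1891 higher and 1710 lower, as its stricter hypothesis implies. Library totals without scaling factors gave 4019 higher and 4992 lower (44.6% higher against 50.0%), and the GC content and length correction, chosen after seeing the data, gave 4751 and 4630. DESeq2 called 4340 higher and 4339 lower. Of the 8937 changed genes, 94.5% kept call and direction with DESeq2 and 95.9% with the GC content and length correction.

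The number of lists past the threshold was 10 with camera's preset correlation, 0 with an estimated correlation (adjusted p of those 10 lists 0.69 to 0.92) and 17 by fry, which tests whether a list's genes move on balance and does not compare them with other genes. It was 9 to 11 with single libraries left out. With library totals the YAP/TEAD list passed as well (adjusted p = 0.043). Of the values of named genes under the alternatives, 1639 kept their side of the threshold, 24 lost a call and 0 passed in the other direction. METTL3, which passed under none, lay between −0.09 and 0.12 on the log2 scale. The cause of the lost list calls was not tested.

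The replicate numbers were not taken to pair libraries, because same-numbered libraries correlated at 0.33, 0.06 and 0.35 in their deviations from the group means, although 5 of 6 libraries correlated best with their own number. Different-numbered libraries correlated between −0.37 and 0.08. The 2nd principal component (6.81% of the variance) placed replicates 1, 2 and 3 in the same order in both groups. Its values were 13.1, 2.81 and −18.1 in the scrambled libraries and 18.9, 4.83 and −21.5 in the knockdown libraries. A shared effect of the replicate number therefore stays open. With the replicate block 4865 genes were higher and 4895 lower, 9 lists passed, and the m6A writer list lost its call (adjusted p = 0.051).

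The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 8937 changed genes, and the highest of the others 0, so 1 split gave as many. For lists, 3 of the 10 splits gave 10 or more. The other splits gave 6 to 11 lists, although none of them had a changed gene. Each of the other splits holds both siRNAs in both groups, in unequal numbers. Part of the siRNA difference thus stays in the comparison, where lists can pass through it. The rest widens the spread within groups, which by itself leaves few changed genes. The splits therefore cannot test whether the changed genes or the lists arose by chance. The number of lists past camera with the preset correlation does not set the real grouping apart from these mixed ones. A list's camera p-value is no measure of how far the groups differ.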

Other observations

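The contractile list, the gene families, the m6A motif test, the hexamer scan and the tests of base composition and USP22 sites were chosen after results of these data had been seen; the tests of site number and of the USP22 copies were set down before their results were seen.

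Genes of smooth muscle contraction and the actin cytoskeleton rose beyond the few named by the rule. In a list of such genes drawn up after ACTG2 and TAGLN had been seen, 23 of 25 were higher and 0 lower, or 24 and 1 adjusted over the list alone, and without those genes 21 of 23 were higher and 0 lower, or 22 and 1 adjusted over the list alone. The median log2 fold change of the 23 was 1.47 (camera p = 2.8e-09, p = 0.031 with an estimated correlation). The filamin FLNA rose from 2253 ± 134 to 5696 ± 177 CPM, vinculin (VCL) from 289 ± 8.98 to 1239 ± 72.4 CPM, the light chain kinase MYLK from 35.7 ± 4.30 to 367 ± 114 CPM and TPM1, a tropomyosin, from 357 ± 15.5 to 986 ± 90.4 CPM. MYOCD, a coactivator of smooth muscle genes, was the 1 lower gene (3.24 ± 0.81 and 1.19 ± 0.96 CPM, adjusted p = 0.064 over all genes). That these genes rose as a group is a hypothesis, since the list was drawn up from the same data.

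Among 79 gene families grouped by symbol, 2 passed camera. Clustered protocadherins of the beta group (PCDHB) were lower in 10 of 17 cases and higher in 0 (adjusted p = 0.032; adjusted p = 0.93 with an estimated correlation), and histone genes were lower in 16 of 26 and higher in 2 (adjusted p = 0.032; adjusted p = 0.93 with an estimated correlation). With an estimated correlation 0 families passed. Transcripts with more GGACT, the core of the m6A consensus, did not differ in fold change from those with fewer across genes, which are not independent replicates (−0.0005 on the log2 scale per motif, SE 0.0041, t = −0.11). The motif number is only a proxy for methylation.

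The hexamers of 3′ UTRs that went with the fold change were few. Among 13030 genes, the 4822 with GAGATG in the 3′ UTR lay 0.27 lower on the log2 scale than genes without it (coefficient −0.27, SE 0.02, t = −13.9), and the 4447 with GAATAT lay 0.31 higher (SE 0.02, t = 15.1). The largest absolute t over 4096 hexamers in 100 permutations of the genes was 4.91. When genes were split at random into 2 sets, GAGATG and GAATAT led the scan in each set. Genes are not independent replicates, and both the permutations and the 2 sets rest on the same 6 libraries. Neither tests whether the hexamers would recur in other libraries. The coefficient of GAGATG was −0.15 (SE 0.02) in coding sequence, and that of its reverse complement in 3′ UTRs was −0.02 (SE 0.02). GAATAT had 0.06 (SE 0.02) in coding sequence, and its reverse complement in 3′ UTRs also had 0.06 (SE 0.02, t = 3.02). The ALKBH5 transcript (2748 bases in GENCODE 29) holds GAGATG once, at position 1026 in the coding sequence, in the context TGGAGATGGA, and no GAATAT; 42.8% of all hexamers occur somewhere in it.

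Base composition was a covariate of the scan, so both coefficients stand beside a linear effect of it. A comparison with other orders of the same bases can therefore address only what that covariate left. For GAGATG, 53 other orders that share few end bases with it reached a lowest t of −2.49, and for GAATAT such orders reached a highest t of 4.41. Over all 59 other orders, most of the added ones overlapping the hexamer, these values were −8.22 and 6.97. Hexamers of A and T such as ATATAT (t = 5.72) passed the permutations, so composition may add to the higher side. A candidate explanation is pairing of the transfected siRNAs with partly matching messages, the ALKBH5 siRNA at GAGATG and the scrambled siRNA at GAATAT. It predicts more effect with more sites, and genes with 2 or more GAGATG lay a further −0.17 (SE 0.03) from genes with 1, and those with 2 or more GAATAT a further 0.19 (SE 0.03). Both hexamers added 3.24% to the variance of the fold change explained and 59.4% of the 6207 genes with neither also changed, against 66.3% of genes with either. The siRNA sequences were not used here, and a microRNA that differed between groups or an effect of ALKBH5 loss stays open, as untested.

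USP22 fell further than the 26 other genes with 5 or more GAGATG sites in a 3′ UTR of similar length. Its 8 GAGATG sites are matched by 0.132% of 1511 genes with a 3′ UTR of similar length, so pairing of the ALKBH5 siRNA with USP22 messages is a candidate explanation of part of its fall. The 26 such genes with 5 or more sites had a median log2 fold change of −0.22 and a lowest one of −2.29, against −3.22 for USP22 and a median of 0.29 for the 461 such genes without a site. By log2 fold change USP22 ranked 4th from the lowest among genes of similar 3′ UTR length. The genes that fell further had fewer than 5 sites, so a fall of this size also occurred without many sites. A move of USP22 reads to the related genes USP27X and USP51 is argued against by their own level: the summed CPM of these genes changed by −1.74% of the fall of USP22. Loss of ALKBH5 itself stays open, since these data hold no knockdown with another siRNA and no rescue.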
